A study of Mus musculus with 24 samples.

How the data were processed

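Total RNA of C2C12 cells, a mouse myoblast line that leaves the cell cycle and fuses into myotubes when it is moved from growth medium to a differentiation medium, was labelled with biotin and hybridised to arrays of 2 designs, whose titles end in MA and MB. Per the labels, the cells carried either the empty pSuperR vector or the same vector with a short hairpin RNA (shRNA, which lowers a messenger RNA by RNA interference) against p68, the DEAD-box RNA helicase encoded by Ddx5, and were kept in growth medium (GM) or differentiation medium (DM). Each design held 4 groups of 3 arrays. Groups and replicate numbers were taken from the titles. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

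The authors deposited 1 intensity per probe set and array on a linear scale. MAS5, which summarises the matched and mismatched probes of a probe set into 1 signal, is named in the submitters' processing notes; its version and settings and the detection calls are not given in the sources used here. From the values, the arrays had already been scaled: with 2% taken off each end, the mean over all probe sets was 150.1 in the MA and 150 in the MB arrays, and the remaining scale factors lay between 0.9999 and 1. Arrays give no count of molecules, so the number of arrays and the spread between them limit the precision. Signals under the pseudocount made up 27.29 to 31.49% of each MA array. In the MB arrays they made up 9.04% in DM vector replicate 2 and 15.62 to 19.96% in the other arrays.

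Probe sets were named through the annotation of the array designs, with symbols compared with the mouse RefSeq gene table of GRCm38.p6, which changed 0 of them; no coordinates were used. Of 22690 MA probe sets, 64 were controls and were left out, 20380 had 1 gene symbol, 691 had several and 1555 had none; the named ones covered 12393 genes. Of 22575 MB probe sets, 64 were controls, 14661 had 1 symbol, 245 several and 7605 none, covering 9607 genes. No gene was named from a probe set with several symbols, and a probe set with no symbol is unnamed here.

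The signals were analysed as log2(signal + 15), the pseudocount being 10% of the trimmed mean. A log2 change is therefore on this scale and understates the change of genes with low signal. A probe set was tested where its signal reached 30, which is 20% of the trimmed mean, in at least 3 of the 12 arrays, which left 14367 MA and 19301 MB probe sets. In limma 3.58.1 (R 4.3.3), 4 group means were fitted to the 12 arrays of a design with 1 shared spread (8 residual degrees of freedom), followed by eBayes with a mean-variance trend and Benjamini-Hochberg adjustment over the probe sets of that design and comparison at a threshold of 0.05. The median residual SD was 0.214 in the MA and 0.523 in the MB arrays. The contrasts were DM against GM in vector cells and in shRNA cells, shRNA against vector in DM and in GM, their difference (the interaction of medium and shRNA) and the average DM against GM change over both constructs. The 2 designs were scaled apart and were tested apart. Values are given as log2 change ± standard error from this fit, over 3 arrays per group, or as mean signal ± SD. Single values of 3 against 3 arrays also had an exact two-sided permutation test, whose smallest possible p is 0.1.

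All of these settings, the alternatives, 23 gene lists and the rule for named genes were written before the data were examined. The rule took, per contrast, the 10 genes (5 in MB) with the largest rise and fall among probe sets with 1 symbol that passed, whose groups did not overlap (not asked of the interaction) and whose higher group mean reached the trimmed mean; up to 4 members per list, those with the largest change among the passing ones or else the highest mean; and always Ddx5, Ddx17, Myod1, Myog, Ckm and Myh3. A gene with several probe sets was given by the one with the highest mean. Outside this rule, Tpm3, Atp2a2, Pdk4, Pvalb and Timp1, which moved against their lists, Sdf2l1, Creld2 and Asns of the unfolded protein response, and some genes changed in both media or in opposite directions were chosen after their values were seen. The lists covered DEAD-box helicases, sarcomere, myogenic transcription factors, calcium handling and neuromuscular junction, myoblast adhesion and fusion, muscle energy metabolism, DNA replication, mitosis, cell cycle exit, p53 targets, interferon response, extracellular matrix, Notch pathway, ribosome biogenesis, RNA splicing, unfolded protein response, cholesterol synthesis, oxidative phosphorylation, ribosomal proteins, and markers of smooth muscle, adipocytes, osteoblasts and cartilage, and macrophages. Only 1 gene, Cdkn1a, stood in both of a pair of lists (cell cycle exit and p53 targets). The lists were tested on the MA design, with 1 probe set per gene, by camera, which compares a list with all other genes, at a preset correlation of 0.01; camera with an estimated correlation and fry were alternatives. List p-values were adjusted over the 23 lists of a comparison. A camera call is written with its adjusted p, and the adjusted p with an estimated correlation is added where that test loses the call.

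The other alternatives were pseudocounts of 1% and 25% of the trimmed mean, no filter and a filter at 50%, no scaling and quantile normalization, eBayes without the trend, only the groups of the contrast in the fit, 1 probe set per gene, the replicate number as a block, and each array left out in turn. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

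The fit was tested on simulated data with the real means and spreads, in which 50 probe sets per size were changed. On the MA design, for log2 changes of 0.5, 1, 2 and 3, it recovered 20, 64, 98 and 100% for DM against GM in vector cells and 16, 62, 98 and 98% in shRNA cells. For shRNA against vector it recovered 30, 68, 94 and 100% in DM and 22, 70, 98 and 98% in GM, and for the interaction 8, 46, 88 and 100%. On the MB design the shares were 2, 8, 44 and 84% for DM against GM in vector cells and 0, 24, 46 and 82% in shRNA cells. For shRNA against vector they were 2, 8, 46 and 70% in DM and 2, 26, 58 and 98% in GM, and for the interaction 0, 4, 24 and 72%. Wrong calls in these simulations numbered 3 to 8 among 128 to 152 calls on the MA and 3 to 4 among 53 to 96 calls on the MB design. Noise was drawn independently for each probe set, and no other probe sets were changed. In the data the number of calls differed, which alters the adjusted threshold, and probe sets may vary together. These shares and wrong calls need not hold there.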

Results

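Gene expression was profiled in C2C12 mouse myoblasts that carried an empty vector or an shRNA against the RNA helicase p68 (Ddx5), in growth medium (GM) or differentiation medium (DM). The stated purpose was to follow muscle differentiation under interference with p68 and its paralogue p72 (Ddx17). The labels name an shRNA against p68 alone. The data comprised 24 arrays, 12 of the MA and 12 of the MB design. Each of the 4 groups of a design had 3 arrays, and this number and the spread between arrays limit the precision. The MA design carried 14367 and the MB design 19301 probe sets above the signal filter. Among the MA arrays, replicate 3 of the vector group in DM stood furthest from its own group, with a mean correlation of 0.951 across probe sets against 0.962 to 0.983 in the other arrays. Among the MB arrays this was replicate 2 of the same group, at 0.825 against 0.835 to 0.886.

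Ddx5, the target of the shRNA, was lower with the shRNA in DM at the probe set with the highest signal. Its signals in DM were 373.1, 302.5 and 302.5 in replicates 1 to 3 with the shRNA and 673.5, 541.0 and 407.9 with the vector, a log2 change of -0.68 ± 0.15 (limma, adjusted p = 0.00678). In GM the signals were 351.4, 388.3 and 376.5 with the shRNA (replicates 2, 3 and 4) and 483.3, 420.4 and 489.2 with the vector (replicates 1, 3 and 4). The change of -0.31 ± 0.15 in GM did not pass (adjusted p = 0.287), nor did the difference between the media (-0.38 ± 0.22, adjusted p = 0.332). With only the arrays of the medium compared in the limma fit, the adjusted p was 0.045 in DM and 0.0904 in GM. In both media the highest shRNA array lay below the lowest vector array, and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow. The other 5 probe sets of Ddx5 did not pass in either medium. Of these, the one with the second highest signal changed by -0.28 ± 0.25 in DM and -0.31 ± 0.25 in GM (adjusted p = 0.497 and 0.551), and the one with the third highest by -0.48 ± 0.18 and -0.49 ± 0.18 (adjusted p = 0.0869 and 0.135). The remaining ones lay between -0.455 and 0.009 in DM and between -0.338 and -0.067 in GM. Ddx17 did not pass with the shRNA. Its probe set with the highest signal changed by 0.10 ± 0.09 in DM and 0.02 ± 0.09 in GM (adjusted p = 0.516 and 0.929). In DM its lowest shRNA array (713.4) lay above its highest vector array (706.3), so the exact permutation p was 0.1 here too. The change in DM was 0.053 without vector replicate 2 of DM, and that in GM lay between -0.004 (without shRNA replicate 3) and 0.069 (without shRNA replicate 4 of GM). This probe set did not pass for DM against GM either, in vector cells (-0.205, adjusted p = 0.0802) or shRNA cells (-0.127, adjusted p = 0.323). A second probe set of Ddx17 was lower in DM than in GM in vector cells (-0.71, adjusted p = 0.000239) and in shRNA cells (-0.39, adjusted p = 0.0238). It did not pass for the shRNA in DM (0.24, adjusted p = 0.214) or GM (-0.08, adjusted p = 0.808).

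**Figure D1:**
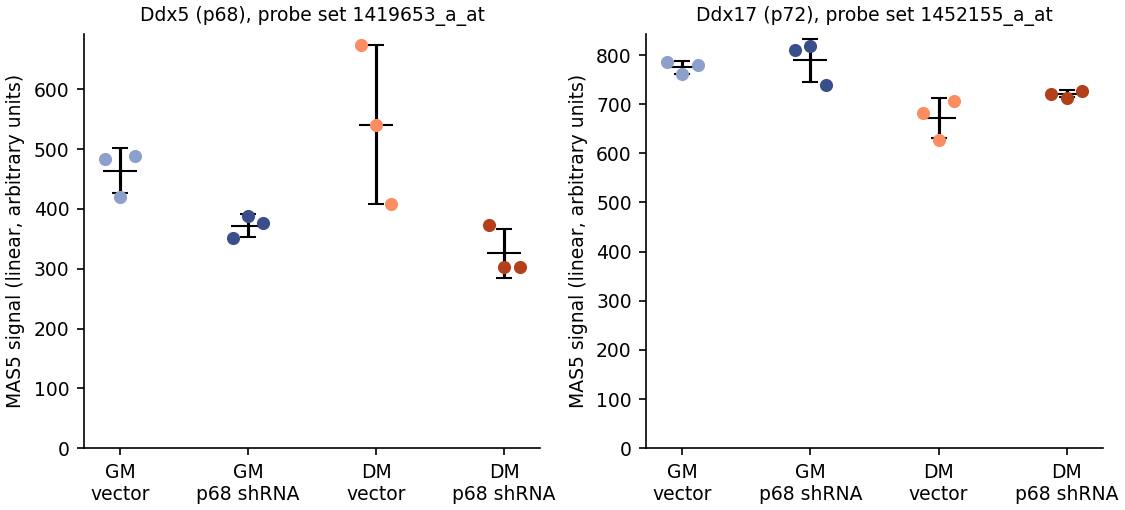
MAS5 signal (linear, arbitrary units) of Ddx5 and Ddx17 in each MA array by medium and construct; points are arrays, and bars give the mean ± SD of 3. The mean for Ddx5 was 540.8 with the vector and 326.0 with the shRNA in DM, and 464.3 and 372.1 in GM, while the groups differed less for Ddx17.

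The comparison of DM with GM in vector cells measured the change of medium without the shRNA. Of the 10 named MA genes that rose most in vector cells in DM, 6 encode proteins of the contractile apparatus of muscle. Myoglobin (Mb), the oxygen-binding protein of muscle, rose from a mean signal of 8.15 ± 6.64 to 8785 ± 2298 (SD, n = 3), a log2 change of 8.58 ± 0.28. The myosin light chain Myl1 rose by 8.01 ± 0.21, the myosin-binding protein gene Mybph by 7.41 ± 0.35 and the embryonic myosin heavy chain Myh3 by 6.83 ± 0.11. Of the troponins that regulate the thin filament, Tnnc2 rose by 7.17 ± 0.18, Tnni2 by 6.86 ± 0.16 and Tnni1 by 6.77 ± 0.18. Ankrd2, Itgb1bp2 (melusin) and the secreted factor Fgf21 rose by 6.89, 6.81 and 6.97. Among the genes that fell were the replication genes Tk1 (-3.83 ± 0.15) and Mcm5 (-3.65 ± 0.18), the mitotic kinesin Kif2c (-3.99 ± 0.13) and cyclin D1 (Ccnd1, -3.47 ± 0.15), which drives entry into the cycle. The potassium channel gene Kcnn4 (-4.33 ± 0.27), matrix Gla protein (Mgp, -4.32 ± 0.16), Tm4sf1 (-4.08 ± 0.10), the AP-1 factor Fosl1 (-3.85 ± 0.25), the water channel Aqp1 (-3.84 ± 0.12) and Igfbp2 (-3.65 ± 0.11) fell as well. The highest adjusted p among these 20 genes was 1.04e-08.

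By gene list, 36 of the 37 measured sarcomere genes rose and the tropomyosin Tpm3 fell by 1.56 ± 0.14 at the probe set used for it. A pair of other Tpm3 probe sets rose, by 1.62 ± 0.20 and 1.60 ± 0.19, so its direction depended on the probe set. The same numbers passed when adjusted over the list alone (median 4.82, camera adjusted p = 2.54e-27, and 0.000943 with an estimated correlation). Calcium handling and neuromuscular junction genes rose in 14 of 17 cases, with the calcium pump Atp2a1 at 6.18 ± 0.15, calsequestrin Casq2 at 6.36 ± 0.15 and the calcium channel subunit Cacna1s at 5.11 ± 0.14. Another calcium pump, Atp2a2, counted as a fall by the probe set used for it (-0.68 ± 0.12), but a pair of its other probe sets rose by 4.20 ± 0.12 and 4.68 ± 0.13, so its direction depended on the probe set (15 and 1 adjusted over the list alone; median 2.11, adjusted p = 4.82e-10). Of 20 muscle energy metabolism genes 17 rose, among them creatine kinase (Ckm, 6.66 ± 0.14) and the muscle forms of cytochrome oxidase Cox6a2 (6.20 ± 0.19) and Cox8b (5.95 ± 0.22), while Pdk4, an inhibitor of pyruvate oxidation, fell by 2.22 ± 0.19 (17 and 1 adjusted over the list alone; median 1.82, adjusted p = 1.11e-10). All 26 DNA replication genes fell (Fen1 -3.33 ± 0.37, Rfc5 -3.17 ± 0.14; median -2.20, adjusted p = 1.22e-15). So did all 23 mitosis genes (Plk1 -3.21 ± 0.13, Birc5 -3.12 ± 0.15, Ube2c -3.03 ± 0.11; median -2.28, adjusted p = 8.48e-14), with the same counts adjusted over the list alone.

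Myogenin (Myog), a transcription factor of terminal muscle differentiation, rose by 6.19 ± 0.17 and its relative Myod1 by 0.55 ± 0.13 (adjusted p = 0.00315). Of the 14 myogenic transcription factors and their inhibitors, 5 rose and 5 fell (6 fell adjusted over the list alone), with Mef2a at 2.94 ± 0.20 and Mef2c at 1.81 ± 0.21 against Id3, an inhibitor of these factors, at -3.35 ± 0.10. The list was not called (adjusted p = 0.952). Oxidative phosphorylation genes rose in 20 of 31 cases and fell in 1 (the same adjusted over the list alone), with Ndufs4 at 2.20 ± 0.20 and Ndufs1 at 1.33 ± 0.17. Camera called the list (median 0.44, adjusted p = 0.000302), but not with an estimated correlation (adjusted p = 0.223). Of 16 p53 targets 9 rose and 1 fell (the same adjusted over the list alone), among them Plk2 (1.85 ± 0.13) and the cell cycle inhibitor Cdkn1a (2.21 ± 0.16). The call (adjusted p = 0.021) was lost at adjusted p = 0.0734 with an estimated correlation. The unfolded protein response list had 11 rises and 5 falls among 18 genes (11 and 7 adjusted over the list alone). Its rising members included the stress transcription factors Atf3 (3.58 ± 0.21) and Ddit3 (2.30 ± 0.14) and Trib3 (2.94 ± 0.21), and its falling ones the chaperone partners Sdf2l1 (-1.73 ± 0.28) and Creld2 (-1.46 ± 0.14). This call (adjusted p = 0.0362) was lost at adjusted p = 0.216 with an estimated correlation.

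The other lists were not called in this comparison. Myoblast adhesion and fusion genes rose in 6 and fell in 7 of 17 cases (Mymk, the fusion protein myomaker, 6.28 ± 0.19; caveolin Cav3 5.14 ± 0.17; integrin Itga3 -2.51 ± 0.17; adjusted p = 0.791). Cell cycle exit genes rose in 8 and fell in 4 of 14 cases (the inhibitor Cdkn1c 6.16 ± 0.21, Gadd45a 3.59 ± 0.20, adjusted p = 0.139). That list holds inhibitors of the cycle and also cyclin D1, which drives it, so its counts give no direction of exit. Notch pathway genes rose in 7 and fell in 4 of 12 cases (the target Hey1 1.74 ± 0.16, the ligand Dll1 1.84 ± 0.15, the ligand Jag2 -1.16 ± 0.16; adjusted p = 0.165). The counts were the same adjusted over the list alone in the last 2 lists, and 7 and 7 in the fusion list. Extracellular matrix genes rose in 7 and fell in 9 of 27 cases (Postn 2.10 ± 0.29, Timp1 -2.68 ± 0.12; adjusted p = 0.952), ribosome biogenesis genes in 8 and 7 of 23 (Fbl -1.54 ± 0.18; adjusted p = 0.952). Cholesterol synthesis genes rose in 3 and fell in 3 of 14 cases (Dhcr7 1.36 ± 0.14, Mvk -1.11 ± 0.13; adjusted p = 0.952). RNA splicing genes rose in 2 and fell in 11 of 27 cases (Ptbp1 -1.58 ± 0.13; adjusted p = 0.175), and DEAD-box helicases in 3 and 6 of 25 (Eif4a2 2.33 ± 0.20; adjusted p = 0.974). Interferon response genes rose in 1 and fell in 3 of 13 cases (the GTPase Igtp 2.52 ± 0.23; adjusted p = 0.974). These 6 lists had the same counts adjusted over the list alone. Ribosomal protein genes rose in 2 and fell in 3 of 20 cases, and none of these passed when adjusted over the list alone, with 5 members at an unadjusted p under 0.05 in limma (adjusted p = 0.952). Markers of other cell types were likewise not called as lists, with equal counts adjusted over the list alone. Smooth muscle markers rose in 2 and fell in 5 of 10 cases (Tagln -1.77 ± 0.15, adjusted p = 0.362). Of the others, 1 of 5 adipocyte markers fell (Cebpa, adjusted p = 0.952 for the list), 1 of 3 osteoblast and cartilage markers fell (Sox9, 0.914), and macrophage markers rose in 1 and fell in 1 of 6 cases (0.952). Sox9 lost its call without vector replicate 1 or 2 of DM (adjusted p = 0.0558 and 0.122) or 1 or 4 of GM (0.0926 and 0.0563). Leaving out 1 array moved some of the smaller counts by over 1.5 times. Without vector replicate 3 of DM, DEAD-box rises numbered 6, splicing rises 8 and ribosomal protein falls 5, and without vector replicate 2 of DM splicing rises numbered 1. Ribosomal protein falls went to 0 in limma without vector replicate 4 of GM, and the rises in that list to 0 without vector replicate 3 of DM or 1 or 3 of GM. The fall of a p53 target stayed only without shRNA replicate 1 or vector replicate 3 of DM.

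In total 3429 probe sets rose and 3649 fell in DM in vector cells (limma, adjusted p under 0.05), of which 1370 and 1414 changed at least 2-fold. Of 23 lists, camera called 8, 5 of them also with an estimated correlation. When these 6 arrays were split into 3 and 3 in other ways, camera at the preset correlation called up to 9. The test fry, which asks whether a list moves on balance in one direction and does not compare it with other genes, called 13. Median, mean and test direction differed in sign in 4 lists, 0 of which were called: the myogenic factors, extracellular matrix, ribosome biogenesis and cholesterol synthesis. The log2 ratio of the 3' to the 5' control probe sets of Gapdh and Actb, a measure of RNA integrity, was lower in DM by 0.093 in the MA vector arrays (exact permutation p = 0.1), in the same arrays as these changes. Without vector replicate 3 of DM, whose ratio of -0.084 was the lowest of the 6, the difference was -0.061.

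With the shRNA in DM, genes of the contractile apparatus and of muscle energy supply were lower than with the vector, and genes of DNA replication, mitosis, cholesterol synthesis and the Notch pathway were higher. Glycogen phosphorylase of muscle (Pygm) had a mean signal of 299.1 with the shRNA and 1332 with the vector (log2 change -2.10 ± 0.22). The perinatal myosin Myh8 changed by -2.05 ± 0.17, the Z-disc proteins Myoz2 and Actn2 by -2.001 ± 0.23 and -1.88 ± 0.14, and the M-band protein Myom1 by -1.95 ± 0.22. Cox6a2 (-1.88 ± 0.19), the stretch-responsive Ankrd1 (-1.90 ± 0.15), the stress-inducible Gadd45a (-1.88 ± 0.20), Gtpbp2 (-1.98 ± 0.13) and Cth, which makes cysteine (-1.85 ± 0.26), also fell. Of the named genes on the MA arrays the carbonyl reductase Cbr2 rose most (2.29 ± 0.11, from a mean signal of 255.0 to 1305). S100a4, a calcium-binding protein of motile cells, rose by 1.94 ± 0.10, the matrix proteoglycan Prelp by 1.89 ± 0.21, the fatty acid desaturase Fads2 by 1.82 ± 0.12 and the fatty acid carrier Fabp5 by 1.71 ± 0.10. Tk1 (1.84 ± 0.15) and the mitotic genes Cdca3 (1.78 ± 0.12) and Bub1b (1.72 ± 0.16) rose too, as did Gstm2 (1.75 ± 0.13) and Hacd4 (1.72 ± 0.14). Of these 20 genes the highest adjusted p was 0.000185, that of Cth.

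Sarcomere genes fell in 25 and rose in 1 of 37 cases (26 and 1 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 9.13e-17). The rise was that of Tpm3, whose probe sets again went both ways (0.48 ± 0.14 for the one used, -0.82 ± 0.20 and -0.94 ± 0.19 for a pair of others), and the count of 1 went to 0 in limma without shRNA replicate 2 or 3 or vector replicate 1 of DM. Muscle energy metabolism genes fell in 13 of 20 cases (15 adjusted over the list alone), among them the hexokinase Hk2 (-1.64 ± 0.15) and the fatty acid carrier Fabp3 (-1.77 ± 0.15), with a median of -0.81 (adjusted p = 2.53e-12). Calcium handling and neuromuscular junction genes fell in 7 of 17 cases (10 adjusted over the list alone), including Cacna1s (-1.58 ± 0.14) and Atp2a1 (-1.32 ± 0.15), while the calcium buffer Pvalb rose by 0.70 ± 0.15 (median -0.40, adjusted p = 9.08e-06). In the other direction, 20 of 26 DNA replication genes rose (24 adjusted over the list alone; Mcm5 1.56 ± 0.18, Pole 1.61 ± 0.17; median 0.81, adjusted p = 1.01e-13). So did 21 of 23 mitosis genes (22 adjusted over the list alone; Ube2c 1.67 ± 0.11, Birc5 1.56 ± 0.15, Mki67 1.48 ± 0.19; median 1.22, adjusted p = 7.04e-18). Cholesterol synthesis genes rose in 13 of 14 cases (13 adjusted over the list alone; Hmgcs1 1.51 ± 0.20, Idi1 1.68 ± 0.28, Mvk 1.23 ± 0.13; median 1.11, adjusted p = 8.3e-11). Notch pathway genes rose in 9 of 12 cases (9 adjusted over the list alone), among them the receptors Notch1 (0.82 ± 0.12) and Notch3 (0.87 ± 0.13) and the target Hes1 (1.30 ± 0.18), with a median of 0.61 (adjusted p = 1.08e-05). Extracellular matrix genes rose in 13 and fell in 1 of 27 cases (19 and 2 adjusted over the list alone; the basement membrane collagen Col4a1 1.21 ± 0.10, the matrix protease Mmp2 1.14 ± 0.11; median 0.50, adjusted p = 1.01e-06).

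Unfolded protein response genes fell in 8 and rose in 2 of 18 cases (10 and 4 adjusted over the list alone), and those that fell included Atf3 (-1.76 ± 0.21), Trib3 (-1.64 ± 0.21), Ddit3 (-1.52 ± 0.14) and the asparagine synthetase Asns (-0.99 ± 0.11), all targets of the transcription factor Atf4. That list was called (median -0.38, adjusted p = 0.00193), but not with an estimated correlation (adjusted p = 0.0571). Ribosome biogenesis genes fell in 3 of 23 cases (3 adjusted over the list alone; Nhp2 -0.62 ± 0.13; adjusted p = 0.00373). The next 3 lists lost their calls with an estimated correlation. Oxidative phosphorylation genes fell in 4 of 31 cases (4 adjusted over the list alone; median -0.22, adjusted p = 0.000276, against adjusted p = 0.181 with an estimated correlation). RNA splicing genes rose in 2 of 27 (2 adjusted over the list alone; median 0.29, adjusted p = 0.0416, against adjusted p = 0.535). Ribosomal protein genes passed singly in 0 of 20 cases in limma, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 (median -0.14, adjusted p = 0.0416, against adjusted p = 0.498 with an estimated correlation).

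Among the factors that control muscle differentiation, Myog (-0.36 ± 0.17, adjusted p = 0.174) and Myod1 (-0.20, adjusted p = 0.359) did not pass for the shRNA in DM, whereas Mef2c fell by 1.13 ± 0.21. The inhibitors Id2 (1.41 ± 0.21) and Id3 (1.14 ± 0.10) and Pax7, a factor of muscle stem cells (0.86 ± 0.14), rose. Of this list, 5 of the 14 genes rose and 1 fell (6 and 1 adjusted over the list alone; list adjusted p = 0.0688). Ckm fell by 0.99 ± 0.14 (adjusted p = 0.000199) and Myh3 by 0.58 ± 0.11 (adjusted p = 0.00257). Myoblast adhesion and fusion genes rose in 7 and fell in 2 of 17 cases (10 and 2 adjusted over the list alone; Myof 1.32 ± 0.25, Cav3 -0.99 ± 0.17; adjusted p = 0.167). Of 25 DEAD-box helicases Ddx5 and Ddx54 (-0.61 ± 0.12) fell (2 adjusted over the list alone; adjusted p = 0.0845). The cell cycle exit list, which mixes inhibitors of the cycle with cyclin D1, had 4 rises and 2 falls among 14 genes (5 and 2 adjusted over the list alone, adjusted p = 0.864). Among the rises was cyclin D1 itself (Ccnd1, 1.63 ± 0.15), a driver of the cycle. Smooth muscle markers rose in 4 of 10 (5 adjusted over the list alone; Lmod1 1.08 ± 0.25; adjusted p = 0.376). The p53 targets (adjusted p = 0.331), the interferon response genes (0.937) and the markers of adipocytes (0.964), osteoblasts and cartilage (0.865) and macrophages (0.937) were not called. Some of these counts moved by over 1.5 times with 1 array left out. Smooth muscle rises numbered 1 without shRNA replicate 1 or 2 of DM, and oxidative phosphorylation falls 2 without shRNA replicate 1 or vector replicate 2 and 8 without vector replicate 1 of DM. Splicing rises numbered 1 without any 1 of the 3 shRNA arrays of DM and 7 without vector replicate 1 of DM, and ribosome biogenesis falls 7 without vector replicate 3 of DM. The rises in the unfolded protein response list went to 0 in limma without any 1 of the 3 shRNA arrays of DM and to 4 without vector replicate 3 of DM.

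In all, 1533 probe sets rose and 897 fell with the shRNA in DM, 317 and 156 of them at least 2-fold. Camera called 13 of 23 lists, 9 of them also with an estimated correlation, and fry called 16. In 2 lists that were not called, the markers of osteoblasts and cartilage and of macrophages, median, mean and test differed in sign. With only the 6 DM arrays in the fit the count was 1574 in place of 2430. The 3'/5' ratio of the control probe sets differed by 0.006 between the constructs in DM (exact permutation p = 0.9), by -0.026 without vector replicate 3 and by 0.031 without vector replicate 2 of DM.

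**Figure D2:**
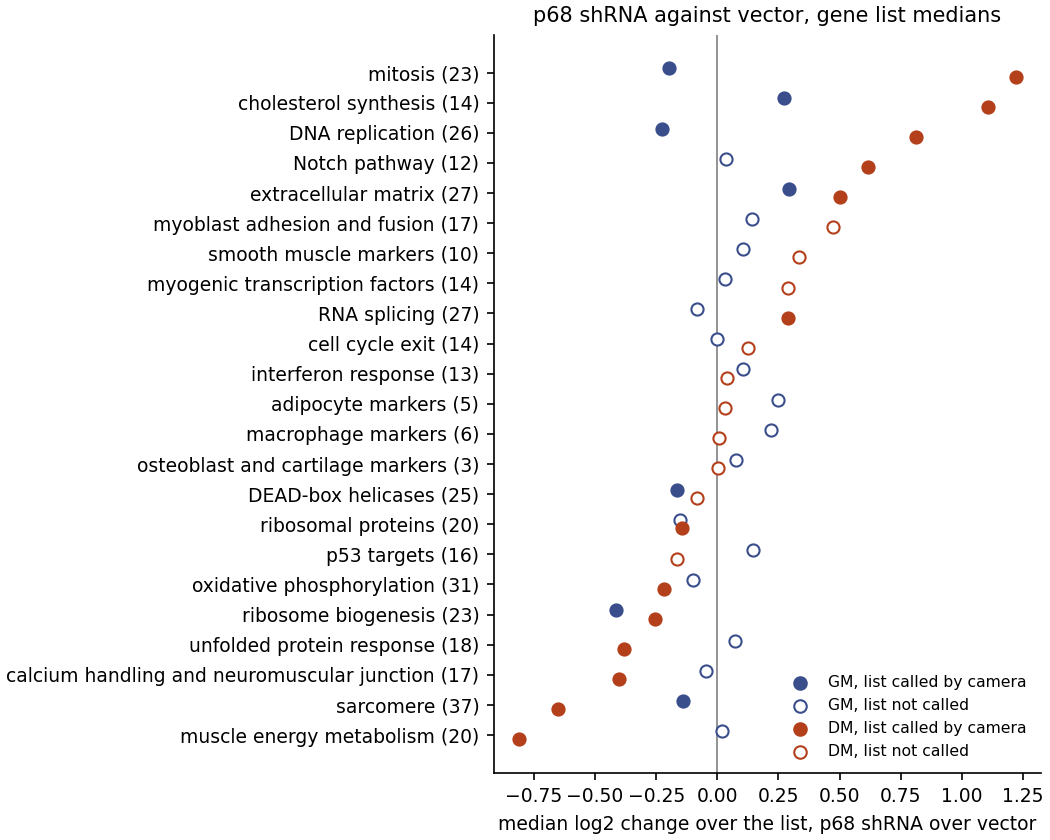
Median log2 change over each gene list, p68 shRNA over vector, in GM (blue) and DM (red), with the number of measured genes in parentheses; filled points are lists called by camera at the preset correlation. In DM the medians ran from -0.81 for muscle energy metabolism to 1.22 for mitosis, and in GM from -0.41 for ribosome biogenesis to 0.29 for the extracellular matrix.

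In GM the extracellular matrix list was higher with the shRNA, a call lost with an estimated correlation (adjusted p = 0.0692), and the ribosome biogenesis list was lower. Sfrp2, a secreted modulator of Wnt signalling, rose by 3.20 ± 0.13, from a mean signal of 262.5 to 2530, and the secreted ligand Gas6 by 3.17 ± 0.13, from 63.65 to 688.2. The matrix proteins Prelp (2.69 ± 0.21) and Fbln7 (2.65 ± 0.19), the plasma selenium carrier Selenop (2.16 ± 0.26), carbonic anhydrase Car3 (2.05 ± 0.17), the growth factor Igf2 (1.95 ± 0.27) and the nuclear long noncoding RNA Neat1 (1.93 ± 0.40) rose too. So did a pair of genes of fat storage and uptake, the lipid droplet protein Plin4 (2.06 ± 0.23) and lipoprotein lipase (Lpl, 1.92 ± 0.17). Genes that fell changed less. They included Errfi1, an inhibitor of the EGF receptor (-1.27 ± 0.13), the collagen Col18a1 (-1.20 ± 0.12), the ribosome assembly factor Grwd1 (-1.09 ± 0.16), the troponin Tnnt2 (-1.07 ± 0.14), and the nucleolar protein fibrillarin (Fbl, -0.99 ± 0.18). The mitochondrial elongation factor Tufm (-0.99 ± 0.17), mesothelin (Msln, -0.98 ± 0.13) and Aif1l (-0.98 ± 0.15) fell as well. The highest adjusted p among these 18 genes was 0.00983, that of Neat1. Kcnn4 (-1.06 ± 0.27, adjusted p = 0.0316) and Klhdc8a (-1.05 ± 0.27, adjusted p = 0.0308) passed as well, but lost the call without any 1 of the 6 GM arrays, with adjusted p from 0.0577 to 0.128 and from 0.0666 to 0.122.

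Extracellular matrix genes rose in 10 and fell in 1 of 27 cases in GM (15 and 2 adjusted over the list alone), with the collagens Col6a1 at 1.43 ± 0.10 and Col6a2 at 1.44 ± 0.11, Thbs2 at 1.13 ± 0.15 and Mmp2 at 1.24 ± 0.11. Timp1, an inhibitor of matrix proteases, fell by 0.71 ± 0.12. The list was called (median 0.29, adjusted p = 6.66e-07) and missed the threshold with an estimated correlation (adjusted p = 0.0692). Ribosome biogenesis genes fell in 6 of 23 cases (12 adjusted over the list alone), with Nhp2 at -0.89 ± 0.13 and Fbl as above, and held the call in both tests (median -0.41, adjusted p = 1.84e-08 and 0.00709). DNA replication genes fell in 5 of 26 cases (9 fell and 1 rose adjusted over the list alone; median -0.23, adjusted p = 0.000248 and, with an estimated correlation, 0.0342). Of these, Rfc5 (-0.60 ± 0.14, adjusted p = 0.0225) lost its own call without any GM array other than shRNA replicate 2, at adjusted p from 0.0642 to 0.0978. Mcm3 (-0.53 ± 0.14, adjusted p = 0.0302) lost it without any 1 GM array, at adjusted p from 0.0544 to 0.127. Mitosis genes fell in 2 of 23 cases (4 adjusted over the list alone; median -0.20, adjusted p = 0.000248, against adjusted p = 0.0732 with an estimated correlation). Of 37 sarcomere genes Tnnt2 and Tnni2 fell and Pdlim3 rose by 0.75 ± 0.16, with equal counts adjusted over the list alone. Tnni2 stood at a mean signal of 40.2 with the vector and 5.602 with the shRNA, both close to or under the filter (-1.43 ± 0.16). The list was called lower (median -0.14, adjusted p = 0.00675), but not with an estimated correlation (adjusted p = 0.201). Cholesterol synthesis genes rose in 1 of 14 cases (3 adjusted over the list alone; adjusted p = 0.0263, against adjusted p = 0.129 with an estimated correlation). DEAD-box helicases rose in 1 and fell in 2 of 25 cases (1 and 3 adjusted over the list alone), with Ddx54 at -0.72 ± 0.12 and Ddx39a at -0.63 ± 0.10 (adjusted p = 0.046, against adjusted p = 0.118 with an estimated correlation).

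The remaining lists were not called in GM. Adhesion and fusion genes rose in 3 and fell in 1 of 17 cases (the same adjusted over the list alone): Cdh2 (0.51 ± 0.11), Jam3 (0.52 ± 0.14) and Ehd2 (0.49 ± 0.13) rose and the cadherin Cdh15 fell (-0.75 ± 0.14). Of 14 myogenic factors Id3 (0.73 ± 0.10) and Id1 (0.45 ± 0.11) rose (the same adjusted over the list alone). Without single GM arrays, Cdh2 lost the call at adjusted p from 0.0514 to 0.0787 (shRNA replicates 2 and 4, vector replicates 1 and 4). Id1 lost it at 0.056 to 0.109 (any but shRNA replicate 3), Ehd2 at 0.0515 to 0.147 (any but shRNA replicate 4) and Jam3 at 0.0559 to 0.13 (any), or 0.0549 without shRNA replicate 1 of DM. Oxidative phosphorylation genes rose in 4 and fell in 2 of 31 cases (7 and 6 adjusted over the list alone), with Ndufs4 at 1.05 ± 0.20. Unfolded protein response genes rose in 3 and fell in 2 of 18 cases (4 and 3 adjusted over the list alone), with Ddit3 at 0.74 ± 0.14, Asns at -0.70 ± 0.11 and Chac1 at -0.82 ± 0.14. Of the Notch genes Hey1 rose (1.08 ± 0.16), with 1 rise and 3 falls adjusted over the list alone. Of the calcium handling genes Pvalb rose (0.87 ± 0.15), with the same count adjusted over the list alone. Ckm changed by -0.53 ± 0.14 (adjusted p = 0.0338) and lost the call without replicate 2 of the shRNA group in DM or without any GM array other than shRNA replicate 2 (adjusted p from 0.0547 to 0.131). Its mean signal was 49.92 with the vector and 30.23, close to the filter, with the shRNA, and the MB probe set of Ckm went the other way without passing (0.80 ± 0.26, adjusted p = 0.348). Adipocyte markers rose in 1 of 5 cases (Lpl; 1 adjusted over the list alone) and smooth muscle markers in 1 of 10 (Synpo2, 0.79 ± 0.16; 3 adjusted over the list alone). Camera called neither (adjusted p = 0.0637 and 0.14), while fry called both higher (adjusted p = 0.00108 and 0.00372). Synpo2 lost its call without shRNA replicate 4 or vector replicate 1 of GM (adjusted p = 0.0516 and 0.0515). Most list counts in GM that are named here moved by over 1.5 times without single arrays. Replication falls went from 5 to 0 in limma without shRNA replicate 4 or vector replicate 1 or 3 of GM and to 9 without vector replicate 3 of DM, and the mitosis falls went to 0 without any 1 GM array. Ribosome biogenesis falls numbered 2 without vector replicate 3 of GM and 10 without vector replicate 3 of DM, and sarcomere falls 6 without the latter. The cholesterol rise was lost without any 1 GM array but vector replicate 4, and oxidative phosphorylation rises numbered 1 without vector replicate 3 of GM. Altogether 573 probe sets rose and 370 fell with the shRNA in GM, 122 and 24 of them at least 2-fold. The count of 943 fell to 551, 543, 497, 496 and 409 without shRNA replicates 2, 3 and 4 and vector replicates 1 and 3 of GM. It was 1469 without replicate 3 of the vector group in DM, which enters only the shared spread. With only the GM arrays in the fit it was 1409, and with only the DM arrays the shRNA in DM gave 1574 in place of 2430. The gap between the media in the number of calls thus depended on the fit. Camera called 7 lists, 2 of them also with an estimated correlation, and fry 9. Median, mean and test differed in sign in 4 lists that were not called (calcium handling and neuromuscular junction, muscle energy metabolism, Notch pathway, oxidative phosphorylation). The 3'/5' ratio of the control probe sets differed by -0.046 between the constructs in GM (exact permutation p = 0.2) and by -0.028 without vector replicate 4 of GM.

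Genes that the shRNA changed in GM and in DM were compared, since the shRNA was present in both media. Of the probe sets that rose in GM, 181 also rose in DM, against 61.1 for independent lists, and 38 fell, against 35.8. Of those that fell in GM, 94 also fell in DM, against 23.1, and 53 rose, against 39.5. Calls in the opposite direction were thus not fewer than in independent lists. Both comparisons use the same estimated spread of a probe set, which can raise such overlaps, so independent lists are not a strict reference. Over all 14367 probe sets, which are not independent replicates, the changes by the shRNA in both media had a Pearson correlation of 0.123 (Spearman 0.094), which was 0.076 without vector replicate 3 of DM. Prelp rose in both (2.69 and 1.89), as did Sfrp2 (3.20 and 1.41 ± 0.13), Fbln7 (2.65 and 1.44 ± 0.19) and Mmp2 (1.24 and 1.14).

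In shRNA cells, muscle genes again rose and cell cycle genes fell in DM. On the MA arrays Mybph (7.65 ± 0.35), Myl1 (7.58 ± 0.21), Mb (7.42 ± 0.28), Tnni2 (7.01 ± 0.16), Tnnc2 (6.74 ± 0.18), Fgf21 (6.55 ± 0.30), Tnni1 (6.53 ± 0.18), Myh3 (6.33 ± 0.11), the cardiac actin Actc1 (6.31 ± 0.21) and the light chain Mylpf (6.26 ± 0.13) rose most, and Myog rose by 6.12 ± 0.17. Mgp (-3.15 ± 0.16), Fosl1 (-3.08 ± 0.25), Sfrp2 (-2.998 ± 0.13), Id3 (-2.94 ± 0.10), Plin4 (-2.90 ± 0.23), the water channels Aqp1 (-2.81 ± 0.12) and Aqp5 (-2.61 ± 0.14), Tinagl1 (-2.76 ± 0.25), Tspan4 (-2.59 ± 0.14) and Tm4sf1 (-2.51 ± 0.10) fell most on these arrays. The sarcomere list rose in 35 and fell in 1 of 37 cases (the same adjusted over the list alone, with adjusted p = 2.39e-36 in camera and 0.000638 with an estimated correlation). Calcium handling genes rose in 14 and fell in 1 of 17 cases (15 and 1 adjusted over the list alone; adjusted p = 1.32e-12) and muscle energy metabolism in 13 and 1 of 20 (15 and 1 adjusted over the list alone; adjusted p = 5.74e-09). Replication genes fell in 24 of 26 cases (25 adjusted over the list alone; adjusted p = 4.94e-13) and mitosis genes in 16 of 23 (16 adjusted over the list alone; adjusted p = 1.19e-06). Notch pathway genes rose in 9 of 12 cases (9 adjusted over the list alone; Notch1 2.17 ± 0.12, Heyl 1.78 ± 0.15; adjusted p = 4e-06). Cholesterol synthesis genes rose in 11 of 14 (11 adjusted over the list alone; Msmo1 2.19 ± 0.21; adjusted p = 1.84e-05) and p53 targets in 7 of 16 (9 adjusted over the list alone; adjusted p = 0.00557). The Notch and cholesterol synthesis lists had not been called in vector cells (adjusted p = 0.165 and 0.952), and their interaction is given below. Unfolded protein response genes, whose call in vector cells was lost with an estimated correlation (adjusted p = 0.216), rose in 7 and fell in 4 of 18 cases (7 and 5 adjusted over the list alone) and were not called in shRNA cells (adjusted p = 0.169), and the call of their interaction was lost in the same way (adjusted p = 0.0839). Oxidative phosphorylation genes rose in 11 of 31 cases (11 adjusted over the list alone; adjusted p = 0.00459, against adjusted p = 0.281 with an estimated correlation). The 11 became 6 without shRNA replicate 2 of DM. Together 2349 probe sets rose and 2520 fell, 814 and 635 at least 2-fold. Camera called 9 lists, 8 of them also with an estimated correlation, and fry 17. Signs differed in 2 lists that were not called, the DEAD-box helicases and the adhesion and fusion genes.

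The interaction of medium and shRNA tested whether the response to DM differed with the shRNA. The rise of muscle genes and the fall of cell cycle genes in DM were both smaller with the shRNA. For Mcm5 the response was -3.65 in vector cells and the interaction 2.16 ± 0.26, and for Tk1 they were -3.83 and 2.09 ± 0.22. Fen1 (2.45 ± 0.53), the polymerase subunit Pole (2.21 ± 0.24), Cdca3 (2.01 ± 0.17), Bub1b (1.99 ± 0.22), Fads2 (2.07 ± 0.16), Fabp5 (2.18 ± 0.15) and Cbln1 (2.00 ± 0.24) had interactions of the same sign. Interactions below 0 were found for Igf2 (-2.99 ± 0.38), Gas6 (-2.39 ± 0.19), Plin4 (-2.34 ± 0.32), the glycogen-binding protein Stbd1 (-2.30 ± 0.16), Myh8 (-2.27 ± 0.24), Ddit3 (-2.26 ± 0.20), Fabp3 (-2.19 ± 0.21), Pygm (-2.12 ± 0.31), Myoz2 (-2.11 ± 0.33) and Plpp3 (-2.07 ± 0.28). Col18a1 fell in DM in vector cells (-2.16 ± 0.12) and rose in shRNA cells (0.74 ± 0.12), with an interaction of 2.90 ± 0.17. For Myog the interaction of -0.07 ± 0.24 did not pass (adjusted p = 0.898), and its standard error leaves a difference between the rises open. For Ckm the interaction of -0.46 did not pass (adjusted p = 0.167), nor did that of -0.51 for Myh3 (adjusted p = 0.0581).

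**Figure D3:**
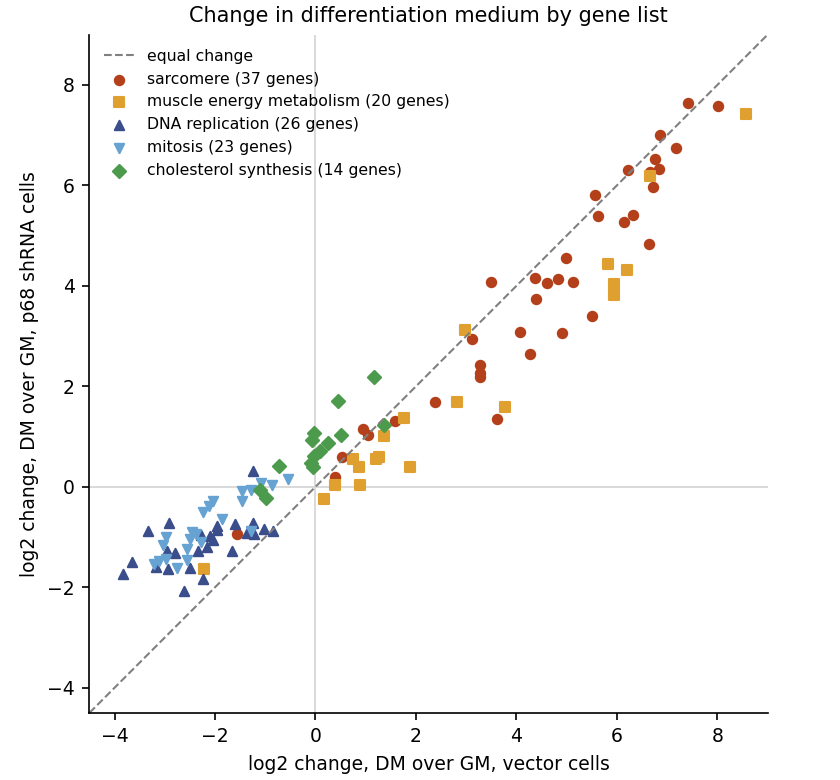
Log2 change from GM to DM in vector cells (horizontal) and in p68 shRNA cells (vertical) on the MA arrays, each point a gene of 1 of 5 lists, with a dashed line of equal change. Most muscle genes lie below the line (median interaction -0.44 for the sarcomere and -0.67 for muscle energy metabolism), and replication, mitosis and cholesterol genes lie mostly above it (1.08, 1.38 and 0.715).

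By list, the interaction passed above 0 in 18 of 26 replication genes (18 adjusted over the list alone, adjusted p = 2.2e-16) and 19 of 23 mitosis genes (22, adjusted p = 1.18e-21). It did so in 10 of 14 cholesterol synthesis genes (13, adjusted p = 3.6e-07) and 6 of 12 Notch pathway genes (6, adjusted p = 0.000335). The number after each count is that adjusted over the list alone. Members outside these counts, here and below, did not pass, whatever their sign. Examples are Aurkb (1.74 ± 0.21), Mvk (1.04 ± 0.18) and Notch3 (1.31 ± 0.18). The interaction passed below 0 in 12 of 37 sarcomere genes (16 below and 2 above, adjusted p = 1.89e-07, with Actn2 at -1.81 ± 0.19 and Csrp3 at -1.85 ± 0.26). It did so in 8 of 20 muscle energy genes (9, adjusted p = 7.54e-09, with Cox8b at -1.92 ± 0.31). The same held in 4 of 17 calcium handling genes (6; adjusted p = 0.000193, against adjusted p = 0.0744 with an estimated correlation; Atp2a1 -1.47 ± 0.21). The unfolded protein response passed below 0 in 6 of 18 genes (9 below and 2 above, with Atf3 at -1.79 ± 0.29, adjusted p = 0.0035, against adjusted p = 0.0839 with an estimated correlation). Oxidative phosphorylation did so in 4 of 31 (6, adjusted p = 0.0107, against adjusted p = 0.411). RNA splicing passed above 0 in 2 of 27 (3, adjusted p = 0.0035, against adjusted p = 0.464). With 1 array left out, the cholesterol count went from 10 to 4 (without shRNA replicate 2 of DM), that of the unfolded protein response from 6 to 3 (without vector replicate 1 of GM) and that of calcium handling from 4 to 7 (without vector replicate 1 of DM). The oxidative phosphorylation count went from 4 to between 1 and 8, the latter without vector replicate 3 of DM. Camera called 10 lists, 6 of them also with an estimated correlation, and fry 12. Signs differed in 2 lists that were not called, the smooth muscle markers and the ribosomal proteins.

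The interaction was called for 1430 MA probe sets, 787 above and 643 below 0. Probe sets were also sorted by the average DM against GM change over both constructs. That average uses the same arrays. The covariance of its error with that of the interaction, estimated from the spread in each group, was -0.0097, and the observed covariance across probe sets, which are not independent replicates, was -0.1846. Of 3859 probe sets higher in DM on average, the interaction was called below 0 in 490 and above 0 in 63. Of 4066 lower ones it was called above 0 in 646 and below 0 in 58 (Fisher's exact test over the called probe sets, which are not independent, p = 3.61e-203). Called or not, its estimate lay below 0 in 72.6% of the higher and above 0 in 76.9% of the lower probe sets. The interaction takes the shRNA change in GM off that in DM, so both media entered it. Over the higher probe sets the median shRNA change was -0.131 in DM and 0.104 in GM. Over the lower ones it was 0.26 in DM and -0.046 in GM. Without replicate 2 of the shRNA group in DM the interaction count was 913 and the 490 became 302, and without vector replicate 3 of DM they were 2050 and 732. Across all probe sets, which are not independent replicates, the responses of vector and shRNA cells had a Pearson correlation of 0.846 (Spearman 0.782). Of the 3429 that rose in vector cells 1879 also rose in shRNA cells, against 560.6 for independent lists, and of the 3649 that fell 2095 also fell, against 640.0. The same estimated spread of a probe set entered both comparisons here too, which can raise the overlap.

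On the MB design, DM against GM in vector cells raised further muscle genes: Ankrd23 (7.10 ± 0.22), the thin filament proteins Lmod3 (6.74 ± 0.27) and nebulin (Neb, 6.69 ± 0.34), Pgm5 (6.54 ± 0.28) and Dhrs7c (6.49 ± 0.23). Dynap (-5.23 ± 0.15), the replication factor Gins2 (-4.64 ± 0.33), Bub1b (-4.57 ± 0.23), the centrosomal pericentrin (Pcnt, -4.09 ± 0.55) and the actin-binding Cotl1 (-3.91 ± 0.24) fell. In total 813 probe sets rose and 965 fell. The 3'/5' ratio of the control probe sets was lower in DM by 0.143 in these vector arrays (exact permutation p = 0.1). In shRNA cells 440 rose and 497 fell (527 changed without the variance trend). The fusion microprotein Mymx (6.23 ± 0.25), Lmod3 (6.23 ± 0.27), Nmrk2 (6.10 ± 0.23), Klhl41 (5.78 ± 0.32) and Ankrd23 (5.76 ± 0.22) rose. Dynap (-3.63 ± 0.15), the glutamate transporter Slc1a3 (-3.57 ± 0.31), the exporter Abcc4 (-3.25 ± 0.39), Trnp1 (-3.003 ± 0.36) and the transglutaminase Tgm5 (-2.96 ± 0.40) fell. The MB probe set of Ckm rose by 1.499 in vector cells (adjusted p = 0.000565), and that of Myod1 did not pass.

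With the shRNA in DM, 151 MB probe sets rose and 75 fell, so 66.8% were higher. With only the arrays of these 2 groups in the fit 101 were called, 45.5% of them higher, so the balance of direction depended on the fit. Bub1b (3.02 ± 0.23), the maintenance DNA methyltransferase Dnmt1 (2.77 ± 0.31), Mss51 (2.45 ± 0.39) and Rtl3 (2.43 ± 0.25) rose, and P2rx3, an ATP-gated ion channel (-3.55 ± 0.51), and Cfap52 (-2.55 ± 0.38) fell. Mybpc2 (-2.98 ± 0.53) and Cox6a2 (-2.38 ± 0.44) fell as well but did not pass without the variance trend. Sgo2a (2.26 ± 0.45) and Rbfox1 (-2.20 ± 0.47) lost their calls under several settings. Sgo2a had adjusted p from 0.0626 to 0.0878 without shRNA replicate 1 or 2 or vector replicate 2 or 3 of DM, and Rbfox1 from 0.0626 to 0.136 without shRNA replicate 1 or 2 or vector replicate 1 or 3. In GM 40 rose and 13 fell, so 75.5% were higher, but without shRNA replicate 1 of GM only 29.4% of 17 calls were. Rtl3 rose (2.62 ± 0.25) and Klhl30 fell (-2.40 ± 0.18) under every setting tried. Aff3 rose by 2.24 ± 0.30, which did not pass with only the GM arrays in the fit, and Snhg3 (-1.57 ± 0.23) and E2f2 (-1.49 ± 0.16) did not pass without the variance trend. Angpt4 (2.54 ± 0.39), Tgm5 (2.40 ± 0.40), Sned1 (2.05 ± 0.42), Prrg3 (-2.26 ± 0.44) and Btbd11 (-1.25 ± 0.20) lost the call with single arrays left out. Angpt4 did so at adjusted p = 0.0926 and 0.0533 without shRNA replicates 1 and 2 of GM, and Tgm5 at 0.0537 to 0.113 without any GM array other than vector replicate 1. Btbd11 did so at adjusted p = 0.0717, 0.0552 and 0.0688 without shRNA replicate 2 and vector replicates 1 and 3 of GM. Without any 1 GM array Sned1 had adjusted p from 0.115 to 0.279 and Prrg3 from 0.092 to 0.198, and both also lost the call without shRNA replicate 1 or 2 of DM (0.0544 to 0.0611), Sned1 without replicate 3 too (0.0548). The 3'/5' ratio differed between the constructs by 0.030 in DM and -0.099 in GM on these arrays (exact permutation p = 0.1 for both), and by 0.013 in DM without shRNA replicate 1.

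The interaction was called for 75 MB probe sets, 43 above and 32 below 0, among them Bub1b (3.14 ± 0.33), Dnmt1 (2.66 ± 0.44), Cfap52 (-3.30 ± 0.53), Aff3 (-3.01 ± 0.42) and Sorbs2 (-2.33 ± 0.37). The MB calls for the shRNA and the interaction rested on the variance trend. Without it limma called 19 probe sets for the shRNA in DM, 9 in GM and 0 for the interaction, where 1478 had an unadjusted p under 0.05 (1632 with the trend). Leaving out single arrays gave 125 to 229 calls for the shRNA in DM, the low values of 126, 125 and 126 without shRNA replicates 1, 2 and 3 of DM. In GM they gave 14 to 71 calls, with 17, 17 and 26 without shRNA replicates 1, 2 and 3 and 14 and 19 without vector replicates 1 and 3. For the interaction they gave 36 to 81 calls, with 48, 39 and 48 without the 3 shRNA arrays of DM, 39 and 40 without shRNA replicates 2 and 3 of GM, and 36 and 44 without vector replicates 1 and 3 of GM. For the 100 probe sets that both designs carry, the changes on MA and MB arrays had Pearson correlations across probe sets of 0.947 for DM against GM in vector cells, 0.858 for the shRNA in DM, 0.783 for the shRNA in GM and 0.740 for the interaction.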

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

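These results stood out because the difference between the responses of vector and shRNA cells, taken as the interaction term, passed. The relabelling of arrays, the fit without the variance trend and the leaving out of each array were chosen before the results were seen, and the tests of a mixture, of scaling and of which calls stayed without an array after. The interaction was called for 1430 MA probe sets, against at most 728 in the other 99 of 100 drawn relabellings of vector and shRNA within each medium, so 1 of 100 was as large. For MB it was called for 75, against at most 27 in the others, and 1 of 100 was as large. This relabelling asked whether the shRNA had any effect, not whether its effect differed between the media. No drawn relabelling swapped the constructs whole in a single medium. The relabelling thus argued against counts this large where the shRNA has no effect, but left chance open for the interaction itself. The median interaction was 1.077 for DNA replication, 1.383 for mitosis, 0.715 for cholesterol synthesis, 0.571 for the Notch pathway and 0.47 for RNA splicing. It was -0.439 for the sarcomere, -0.669 for muscle energy metabolism, -0.568 for calcium handling and neuromuscular junction, -0.494 for the unfolded protein response and -0.202 for oxidative phosphorylation. With an estimated correlation 4 of these lists lost the call: RNA splicing (adjusted p = 0.464), calcium handling (0.0744), the unfolded protein response (0.0839) and oxidative phosphorylation (0.411).

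Single MA genes with an interaction above 0 were Col18a1 (2.904), Fen1 (2.45), Pole (2.207), Fabp5 (2.177), Mcm5 (2.157), Tk1 (2.093), Fads2 (2.069), Cdca3 (2.01), Cbln1 (1.999) and Bub1b (1.99). Those below 0 were Igf2 (-2.988), Gas6 (-2.391), Plin4 (-2.342), Stbd1 (-2.301), Myh8 (-2.271), Ddit3 (-2.258), Fabp3 (-2.19), Pygm (-2.123), Myoz2 (-2.111) and Plpp3 (-2.069). On the MB arrays they were Bub1b (3.145), Cdh26 (2.987), Dnmt1 (2.663), Egr3 (2.5) and Mapk14 (2.396), and Mybpc2 (-3.586), Cfap52 (-3.304), Aff3 (-3.012), Sorbs2 (-2.328) and Prkag3 (-2.192). All of these MB genes lost the call without the variance trend.

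With the shRNA in DM, muscle genes were lower and cell cycle genes higher than with the vector. A share of undifferentiated cells mixed with cells like those of the vector culture would lower all strongly induced muscle genes by about the same amount, but the variance of their changes was 7.62 times that of their errors (32 genes, 95% interval 4.11 to 11.1), which argued against it as the whole cause, although compression that differs between probe sets could also widen the spread. Over the 11 of these genes with a mean vector signal under 2000 in DM, the ratio was 11.2 (3.7 to 18.8). Scaling of the arrays would move all lists alike, and the median of mitosis minus that of the sarcomere was 1.872, which argued against it. Replicate 3 of the vector group in DM was argued against as the source, since without it 2050 probe sets were called, 1368 of the 1430 among them with the same sign; the count was 913 without shRNA replicate 2 of DM, and with any 1 array left out the median in DM stayed between -0.739 and -0.628 for the sarcomere and between 1.178 and 1.265 for mitosis. The knockdown of p68 itself was not tested against differences between the vector and shRNA cell pools, since 1 shRNA was used.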

How the results depend on the processing

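Except for the replicate block, the alternatives below moved a result; the cause was not tested. Counts of changed MA probe sets with 1 probe set per gene were 4391 for DM against GM in vector cells, 3105 in shRNA cells and 4878 on average, from fewer features. With only the groups of the contrast in the fit, the shRNA in DM gave 1574 on MA and 101 on MB arrays, and the share higher on MB went from 66.8% to 45.5%. The correlation of the responses of vector and shRNA cells was 0.832 with a pseudocount of 1% of the trimmed mean, 0.808 with no filter, 0.872 with the filter at 50% and 0.861 with 1 probe set per gene, and 0.833 to 0.845 when 1 array was left out. Lists called for DM against GM in vector cells were 5 by camera with an estimated correlation and 13 by fry, in shRNA cells 17 by fry, for the shRNA in GM 2 and for the interaction 6 by camera with an estimated correlation. On MB without the variance trend limma called 19 for the shRNA in DM, 9 in GM, 527 for DM against GM in shRNA cells and 0 for the interaction (1478 at unadjusted p under 0.05), and quantile normalization gave 92 for the shRNA in GM. Leaving out 1 array gave 409 to 1469 for the shRNA in GM on MA, 913 to 2050 for the MA interaction, 302 to 732 for the interaction among probe sets higher in DM on average, and on MB 125 to 229 for the shRNA in DM, 14 to 71 in GM and 36 to 81 for the interaction. For Ddx17 in GM it gave -0.004 to 0.069, reversed at -0.004 without shRNA replicate 3. With a replicate block the MA counts stayed within 1.5 times, at 6812, 2566, 919, 4520 and 1366 for DM against GM in vector cells, the shRNA in DM and in GM, DM against GM in shRNA cells and the interaction. Arrays with the same number in different groups correlated at -0.139 to 0.293 on MA (6 of 13 pairs over 0.1, against 5 of 41 with different numbers) and -0.039 to 0.07 on MB (0 of 18). Since not every pair was over 0.1, the numbers were not used to pair the samples. That rule cannot exclude a link by number on MA, where the median was 0.093 for same-numbered and -0.024 for other pairs. Of 11494 alternative values for 557 named results, 647 no longer passed and 0 were reversed.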

Other observations

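The genes in this part were chosen after their values were seen. Several genes were higher with the shRNA in both media on the MA arrays. The scavenger receptor Scara5 rose by 1.825 in GM and 1.664 in DM, Fndc1 by 1.621 and 1.506, the heparan sulfatase Sulf2 by 1.345 and 1.242, Igfbp3 by 1.188 and 1.687, the ribonuclease Rnase4 by 1.175 and 1.481 and the chemokine Cxcl12 by 1.151 and 1.63. Igfbp3 (1.074 and 1.381) and Sulf2 (0.957 and 1.242) also rose in both media on the MB arrays. Among the genes lower in both media, Phgdh changed by -0.708 in GM and -0.912 in DM, Shmt2 by -0.924 and -1.231, Mthfd2 by -0.833 and -0.878 and Asns by -0.698 and -0.986.

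A few genes passed in opposite directions in DM against GM. Gas6 rose by 1.677 in vector cells and changed by -0.714 in shRNA cells, and Sat1 (1.191 and -0.79), Rassf1 (0.611 and -0.651), Npnt (0.668 and -0.581) and Smpdl3b (0.733 and -0.559) behaved alike. The reverse held for Col18a1 (-2.163 and 0.741), Tead2 (-0.835 and 0.724), Olfm1 (-0.611 and 0.901), Lamb1 (-0.71 and 0.569) and the Notch genes Hes1 (-0.582 and 0.916) and Notch3 (-0.432 and 0.877).

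The splits of arrays and the test of equal numbers below were chosen before the results were seen, and the tests of the GM changes and of the MB counts after. There were 10 splits of 6 arrays into 3 and 3, too few for a share under 0.05, and the real one alone had the largest count of changed probe sets in every comparison (1 of 10). On MA these counts were 6289 for DM against GM in vector cells, 1574 for the shRNA in DM, 1409 in GM and 5565 for DM against GM in shRNA cells, and on MB 1470, 101, 44 and 1063. Every other split gave 0 calls in limma, with at most 473, 1066, 595 and 374 (MA) and 795, 1166, 1123 and 836 (MB) at unadjusted p under 0.05. For the lists, camera called 8 in vector cells, but 3 of the 10 splits were as large, with up to 9 lists. It called 12, 8 and 9 in the other comparisons in the same order, where 1 of 10 was as large and other splits reached 9, 6 and 8. Camera at the preset correlation thus called as many lists in some other splits as in the real one in vector cells. The average DM against GM change was called for 7925 MA probe sets against at most 4126 in the other relabellings, 1 of 100 being as large. This argued against media that have no effect in either construct.

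In GM the changes with the shRNA might have come from cells further into differentiation or cycling more slowly. The sarcomere list had a mean change of -0.188 (95% interval over genes -0.318 to -0.065), but over the 19 members above the filter the interval of -0.302 to 0.05 included 0. Of the 3859 MA probe sets higher in DM on average, 226 were called higher and 76 lower with the shRNA in GM. Of the 4066 lower ones, 186 were called higher and 213 lower (Fisher's exact test over the called probe sets, which are not independent, p = 3.7e-14). On MB the same counts were 10 and 6, and 14 and 5. The sarcomere list and the MA probe sets higher in DM thus pointed in different directions. Whether the cells were further into differentiation could not be told. The replication mean of -0.218 (-0.339 to -0.088) and the mitosis mean of -0.208 (-0.274 to -0.145) were consistent with slower cycling, all shRNA arrays lying below all vector arrays (exact permutation p = 0.1). These intervals treat genes as independent. Whether slower cycling accounts for the changes of Sfrp2 and Gas6 was not tested.

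MB arrays gave fewer calls than MA arrays. The residual SD was larger on MB in 6 of 6 bins of signal. The 100 probe sets on both designs, however, had a median signal of 359.2 on MA and 2265 on MB. An equal signal thus did not mark an equal level on both designs. The bins could not tell whether replicates varied more. On these shared probe sets the median standard error for DM against GM in vector cells was 0.133 on MA and 0.169 on MB. Smaller changes on MB stayed open. The SD of DM against GM changes on the 100 shared probe sets had a ratio of 1.023 (0.961 to 1.105) of MB to MA, but these measure the same transcripts on both designs and had a median signal of 2265 on MB, so they say nothing of the other MB probe sets. Arrays of the same number on both designs may carry the same RNA: their deviations over shared probe sets correlated by 0.562 more than those of other pairs (exact permutation p = 0.000772, one-sided, the smallest of 1296 relabellings; 10 pairs against 26).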
